A study of Mus musculus with 6 samples.

How the data were processed

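The samples were Tregs from mouse spleen, 3 libraries labelled Etv3+/+ and 3 labelled Etv3-/-, from mice that per the labels carry a Foxp3-GFP reporter. Per the labels' protocols, spleens were dissociated mechanically, red cells were lysed, CD4+ T cells were enriched by depleting other lineages with magnetic beads, and live CD4+ GFP+ cells were sorted to a purity that the labels put above 95%. RNA was column-purified with DNase, and cDNA libraries were made with a SMART-Seq HT low-input kit. No strand setting is given in the sources used here, so antisense and overlapping genes cannot be told apart.

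Per the submitters' processing notes, the authors used bcl2fastq, Trimmomatic, STAR, featureCounts and DESeq2 with build mm10. Versions, parameters and the gene annotation are not given in the sources used here. The deposited files held 2 matrices of 55291 genes, and each was read by its library column names. The first holds raw counts, deposited as whole numbers of reads per gene. The second holds a normalized signal that the authors made by dividing each library's counts by 1 size factor. Multiplied back, it gave the raw counts to within 0.00132 counts, and its factors (0.855 to 1.52) equalled those of DESeq2 on the raw matrix to a relative difference of 2.6e-09. The raw counts were used for every result. The table held no row of unassigned reads. Of the symbols, 96.4% are in GENCODE vM21, whose mm10 coordinates are printed for genes with 1 position.

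Genes were kept by edgeR's filterByExpr (16042 of 28556 with any count) and normalized by TMM. The main test was edgeR's quasi-likelihood F test (robust fit, genotype as the only term, 2-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p without another name is from this test. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic, and values per group are TMM-scaled CPM, mean ± SD over 3 libraries. With 3 against 3 libraries an exact permutation test of 1 gene cannot give a p under 0.10, so single genes were tested only in the model across genes. Precision follows depth: 3 counts in a library correspond to 0.0442 to 0.0785 CPM, and intervals and floors cover counting error only. The replicate numbers were not used as pairs.

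Before the data were examined, 35 gene lists were fixed: Treg core, effector and resting genes, signalling, helper programme, metabolic, cell cycle, stress and ribosomal lists, and markers of B, plasma, myeloid, neutrophil, erythroid and platelet, CD8 T and NK, and conventional CD4 T cells. The 33 lists with at least 5 tested genes were tested with camera (limma) on log2 CPM (prior count 2) with a correlation of 0.01, adjusted over lists. Named genes were also fixed by rule: Etv3, the 10 largest positive and the 10 most negative log2 fold changes among called genes with non-overlapping groups and a mean of at least 1 CPM (leaving out predicted, clone-named, pseudogene and receptor segment names), and up to 4 members per list with the smallest p. Under that rule 146 genes qualified, 107 higher and 39 lower, and 18 called genes had names of the kinds left out. Foxp3, Il10, Jun, Jund, Dnaja1, Penk, Atp6v0d2, Cd79a, Ighm, Fcrl1, Fam160a1, Glt28d2, Gm37240, Insrr and the genes of the closing section's opening paragraph were chosen after their values were seen.

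The analysis was tested on simulated data with 200 changed genes drawn from the real means and library sizes, run on 15371 genes. The test recovered 51.6% of the 2-fold and 58.9% of the 4-fold changes of this comparison, with median estimates of 1.00 and 2.06 on the log2 scale and 7 false calls among 109. In a second simulation that shifted the effector Treg list alone, camera called that list and 1 of the other lists, several of which share its members. Genes were simulated independently of each other, while the estimated correlation of the effector list in the real data was 0.16. This simulation therefore cannot show how often camera with the preset correlation calls lists whose members move together. Alternatives were RLE, upper-quartile and total-count scaling, DESeq2, limma-voom with and without quality weights, another low-count filter and none, the replicate number as a block, leaving out each library, a threshold of 0.1, and for lists an estimated correlation and fry. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.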

Results

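The data were bulk RNA-seq counts from regulatory T cells (Tregs) sorted from mouse spleen as live CD4+ cells carrying the Foxp3-GFP reporter. The labels give 3 libraries as Etv3+/+ and 3 as Etv3-/-, here called wildtype-labelled and knockout-labelled, where Etv3 is an ETS-family transcription factor. The comparison asked which transcripts of splenic Tregs differ between these labels. Wildtype-labelled libraries 1, 2 and 3 held 66615618, 39987344 and 48477071 counts, knockout-labelled libraries 1, 2 and 3 held 41570478, 40505224 and 38969508, and 16042 genes were tested. The labels do not say whether the 3 libraries of a genotype came from separate mice, so the p-values measure the spread between these libraries.

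Etv3 itself did not separate the genotypes. Its level was 85.8, 94.3 and 127 CPM (counts scaled to library size) in wildtype-labelled libraries 1, 2 and 3, and 129, 126 and 101 CPM in knockout-labelled libraries 1, 2 and 3. The log2 fold change was 0.21 ± 0.17 (SE, n = 3 per group), with an edgeR adjusted p of 0.602. Etv3 lies on the plus strand of chromosome 3 from 87525407 to 87540156 (mm10) and is protein-coding. A count over the whole gene checks the genotype only if the deletion removes most of the transcript, and the exons that were deleted are not given in the sources used here. Each direction below therefore rests on the genotype labels and not on a measured loss of Etv3 transcript. The other 14 tested genes of the ETS family list did not pass either. The nearest were Ets2 (39.3 ± 2.42 CPM in wildtype-labelled and 71.6 ± 18.9 CPM in knockout-labelled libraries, SD, n = 3 each, adjusted p = 0.0743), Ets1 (3036 ± 62.8 against 2434 ± 167 CPM) and Elk3 (53.4 ± 3.80 against 69.4 ± 8.44 CPM), and the list had a camera adjusted p of 0.221, with 1 member higher adjusted over the list alone.

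The 6 libraries separated by label on the first principal component but not by every measure. That component, with 30.7% of the variance, ran from -65.0 to -15.3 in the wildtype-labelled and from 31.9 to 57.8 in the knockout-labelled libraries. Spearman correlations of log2 CPM across genes were 0.978 to 0.979 between knockout-labelled libraries, 0.966 to 0.971 between wildtype-labelled ones and 0.961 to 0.971 across genotypes.

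Between genotypes, 124 genes rose and 48 fell in the knockout-labelled libraries (172 genes, edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 118 changed at least 2-fold, 97 upward and 21 downward. In all 172 genes the 3 knockout-labelled values lay on one side of the 3 wildtype-labelled values, as they did in 22.2% of all tested genes, where chance gives 10%. The count moved with the libraries used: it was 3 without wildtype replicate 1, 109 without wildtype replicate 2, 384 without wildtype replicate 3, 67 without knockout replicate 1, 27 without knockout replicate 2 and 11 without knockout replicate 3. Fgl2 and Atp6v0d2 passed in each of these 6 fits, and all 172 genes kept their direction in each.

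Among called genes that the naming rule admits, Atf3, Lrrn4 and Crppa, all nearly absent from the wildtype-labelled libraries, had the largest fold changes, followed by the heat shock gene Hspa1a. Hspa1a, a stress-induced HSP70 chaperone, rose from 4.52 ± 1.18 to 129 ± 66.0 CPM (SD, n = 3 each; log2 fold change 4.82 ± 0.40, SE; adjusted p = 0.00259). Its neighbour Hspa1b rose from 43.5 ± 25.5 to 977 ± 407 CPM (log2 fold change 4.49 ± 0.45). Both are near-identical copies, so the split of reads between them is uncertain. Atf3, a stress-induced bZIP factor, had 0 counts in each wildtype-labelled library. It had 0.840, 8.30 and 10.4 CPM in knockout-labelled libraries 1, 2 and 3 (6.52 ± 5.03 CPM). That mean is at least 109-fold higher against a floor of 3 counts per library, which does not hold for knockout-labelled library 1 alone. Mmp9, a secreted gelatinase, rose from 1.46 ± 1.33 to 40.2 ± 14.9 CPM, and Il13ra1, an IL-13 receptor chain, from 0.445 ± 0.482 to 8.75 ± 1.89 CPM. Cxcl2, a neutrophil-attracting chemokine, went from 0.503 ± 0.233 to 5.51 ± 1.68 CPM, Lilr4b, an inhibitory leukocyte receptor with a close paralog, from 1.45 ± 0.410 to 14.9 ± 5.35 CPM, and Cc2d2a, a ciliary gene, from 1.11 ± 0.657 to 10.2 ± 1.48 CPM. Lrrn4 and Crppa had only 4 and 6 counts in the wildtype-labelled libraries against 380 and 288, ratios of 125 (95% counting interval 48.5 to 462) and 63.2 (28.7 to 174).

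The most negative fold changes included the T cell receptor gamma constant genes. Trgc4 fell from 12.3 ± 6.14 to 1.54 ± 0.539 CPM (adjusted p = 0.0244), Trgc1 from 16.3 ± 5.76 to 2.30 ± 0.744 CPM (log2 fold change -2.82 ± 0.36, adjusted p = 0.0126) and Trgc2 from 8.78 ± 1.34 to 1.56 ± 0.748 CPM (adjusted p = 0.0256). These constant genes resemble each other, so their separate values are uncertain. The interferon-induced gene Ifit3 fell from 44.2 ± 7.08 to 14.8 ± 6.34 CPM and its close copy Ifit3b from 13.7 ± 4.05 to 3.43 ± 1.43 CPM. Myb, a transcription factor of lymphocyte development, fell from 35.3 ± 11.5 to 14.2 ± 1.71 CPM, and Socs2, a cytokine signalling inhibitor induced by STAT5, from 86.1 ± 15.6 to 35.6 ± 3.27 CPM. Ampd1 (AMP deaminase), Dnah7a (an axonemal dynein chain) and Tlcd1 also fell (log2 fold changes -1.92, -1.93 and -1.92).

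**Figure D1:**
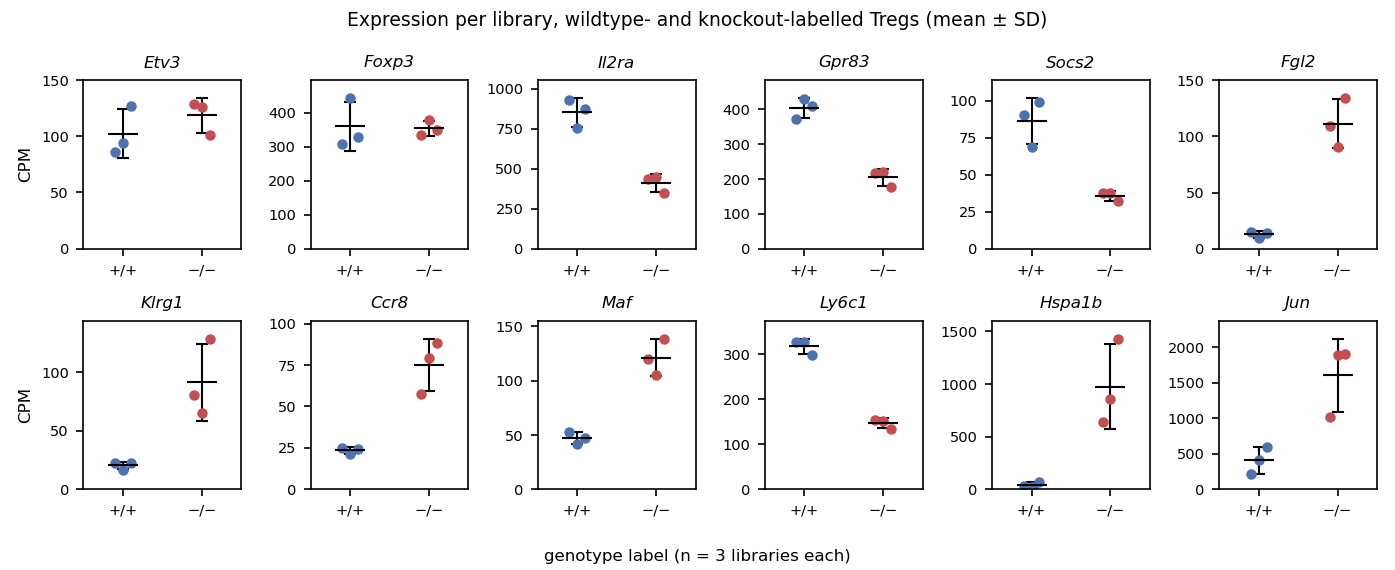
Expression in CPM (linear axis from 0) of 12 genes, each point a library, with the mean and SD of 3 libraries per genotype label. Etv3 and Foxp3 overlap between the groups, Il2ra, Gpr83, Socs2 and Ly6c1 lie lower and Fgl2, Klrg1, Ccr8, Maf, Hspa1b and Jun higher in each knockout-labelled library.

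Some genes of effector Tregs rose in the knockout-labelled libraries. Of 30 tested members of the effector Treg list, 11 rose and none fell, and 18 rose when adjusted over the list alone. Fgl2, a secreted suppressor molecule of Tregs, rose from 12.7 ± 3.19 to 111 ± 22.0 CPM (log2 fold change 3.13 ± 0.23, adjusted p = 0.00133). Klrg1, a marker of terminally differentiated effector cells, rose from 20.5 ± 3.21 to 91.4 ± 33.0 CPM (2.16 ± 0.25), Ccr8, a chemokine receptor of tissue and effector Tregs, from 23.6 ± 1.98 to 75.0 ± 15.8 CPM (1.67 ± 0.18), and Maf, a transcription factor of IL-10 producing T cells, from 47.6 ± 5.56 to 121 ± 16.7 CPM (1.35 ± 0.15). Batf, Tigit, Ccr2, Itgb1, Areg, Cxcr3 and Gata3 completed the 11. Il10 went from 2.82 ± 2.90 to 23.0 ± 7.96 CPM without passing (adjusted p = 0.0706). The median member had a log2 fold change of 1.04 (camera adjusted p = 5.4e-16, adjusted p = 0.218 with an estimated correlation, and fry adjusted p = 0.0241). The estimated-correlation setting also raised the adjusted p of lists whose estimate lay below the preset 0.01, so it does not isolate the effect of correlated members.

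A few resting Treg genes fell. The list had a median log2 fold change of -0.22, with 2 of 20 members lower and none higher over all genes, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00214, and adjusted p = 0.280 with an estimated correlation). Ly6c1, a surface antigen of resting T cells, fell from 318 ± 16.8 to 147 ± 11.3 CPM (log2 fold change -1.11 ± 0.11, adjusted p = 0.00627), and Igfbp4 from 67.2 ± 12.3 to 34.9 ± 1.91 CPM. Bcl2, a survival factor, had 377 ± 99.1 against 233 ± 21.7 CPM (adjusted p = 0.0999). Klf2, a regulator of T cell trafficking, went against the list, with 235 ± 96.1 CPM in wildtype-labelled and 582 ± 215 CPM in knockout-labelled libraries (adjusted p = 0.101).

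Core Treg identity genes split. The sort marker Foxp3 had 360 ± 72.2 CPM in wildtype-labelled and 354 ± 21.5 CPM in knockout-labelled libraries (log2 fold change -0.02 ± 0.15, adjusted p = 0.959), and the sign of this difference turned in 3 of its alternative fits. Il2ra, the high-affinity IL-2 receptor chain, fell from 854 ± 89.3 to 411 ± 56.2 CPM (-1.06 ± 0.14, adjusted p = 0.0126), as did Gpr83, a receptor enriched in Tregs, from 404 ± 28.4 to 205 ± 23.7 CPM (-0.98 ± 0.12), and Socs2. Ebi3, a subunit of IL-35 and IL-27, rose from 7.13 to 24.1 CPM, and Penk, the proenkephalin gene, from 76.4 to 155 CPM. The remaining 18 of 23 members did not pass, and the list as a whole did not pass (median 0.17, camera adjusted p = 0.166). Adjusted over the list alone, 6 rose and 3 fell. The IL-2 and STAT5 list, which also holds Il2ra and Socs2, had 1 of 24 members higher (Nfil3, 10.6 ± 3.90 to 46.4 ± 19.0 CPM) and 2 lower. Adjusted over the list alone these were 4 and 5, and its median of -0.07 and mean of 0.08 differed in sign (camera adjusted p = 0.667, direction down).

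Genes of helper T cell programmes rose in small numbers. Cxcr3, Ccr8, Areg, Gata3, Batf and Maf, given below, are also among the effector Treg calls above, so these lists do not add independent evidence. In the Th1 list, Ifng (interferon gamma) rose from 2.03 ± 0.359 to 13.3 ± 4.68 CPM (log2 fold change 2.71 ± 0.35) and Cxcr3, a chemokine receptor of type 1 cells, from 26.6 ± 11.2 to 91.4 ± 20.6 CPM. These were 2 of 18 members, or 7 adjusted over the list alone (camera adjusted p = 5.6e-04, and 0.218 with an estimated correlation). Of 12 Th2 list members, 3 rose, namely Ccr8, Areg (amphiregulin, a tissue-repair growth factor, 1.86 ± 0.753 to 14.4 ± 6.11 CPM) and Gata3 (248 ± 33.8 to 396 ± 24.1 CPM), or 5 adjusted over the list alone (camera adjusted p = 0.00109, and 0.218 with an estimated correlation). The Th2 list shares 5 members with the effector Treg list. In the follicular list, Il1r2, a decoy IL-1 receptor, rose from 15.8 ± 1.61 to 50.7 ± 8.31 CPM, Tox2 from 7.85 ± 4.22 to 53.3 ± 10.4 CPM, and Maf rose as above, 3 of 17 members or 6 adjusted over the list alone. Its camera adjusted p was 0.00339, and 0.313 with an estimated correlation. Of 9 Th17 list members only Batf rose (56.6 ± 3.79 to 112 ± 6.72 CPM), or 4 adjusted over the list alone (camera adjusted p = 0.0209, and 0.218 with an estimated correlation). That call was lost without wildtype replicate 2 (adjusted p = 0.0539).

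Of 26 tested members of the chemokine and homing receptor list, 4 rose (Ccr8, Ccr2, Itgb1 and Cxcr3, all among the effector Treg calls above), or 11 adjusted over the list alone. Ccr2, an inflammatory chemokine receptor, rose from 15.6 ± 2.86 to 39.2 ± 4.57 CPM and Itgb1, the integrin beta-1 chain, from 296 ± 45.5 to 648 ± 121 CPM. The median log2 fold change of the list was 0.46 (camera adjusted p = 3.9e-06, and 0.218 with an estimated correlation). Of 16 co-inhibitory receptors, only Tigit, also an effector Treg call above, rose (24.8 ± 2.89 to 63.1 ± 11.4 CPM, adjusted p = 0.0126). Adjusted over the list alone, 3 were higher and 1 lower. Ctla4 had 499 ± 87.3 against 803 ± 151 CPM without passing (adjusted p = 0.0920), and Cd160 had 30.1 ± 5.80 against 17.7 ± 0.439 CPM (adjusted p = 0.0867). The list's camera adjusted p was 0.0233, and 0.313 with an estimated correlation, and it was lost without wildtype replicate 3 (0.104) and without knockout replicate 3 (0.0677).

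Several stress and immediate early genes rose in the knockout-labelled libraries. All 23 members of the dissociation and immediate early list had positive log2 fold changes, 8 passed over all genes and 22 adjusted over the list alone (median 1.16, camera adjusted p = 1.8e-16, and adjusted p = 0.218 with an estimated correlation of 0.45). Besides Hspa1a, Hspa1b and Atf3, the chaperone genes Dnajb1 (205 ± 35.8 to 543 ± 83.4 CPM), Hsph1 (80.5 ± 13.1 to 167 ± 21.1 CPM) and Dnaja1 and the AP-1 genes Jun (408 ± 190 to 1607 ± 513 CPM) and Jund rose. The mean log2 CPM of this list was 6.27, 6.35 and 7.02 in the wildtype-labelled and 7.92, 8.66 and 8.59 in the knockout-labelled libraries, so it moved with the same label as the effector genes.

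**Figure D2:**
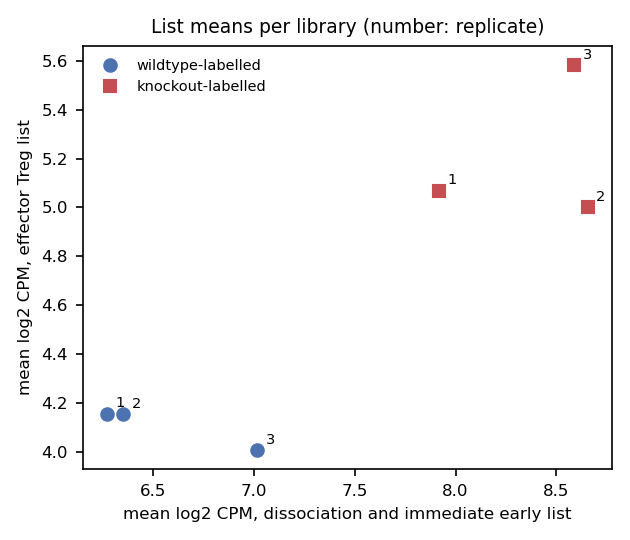
Mean log2 CPM of the effector Treg list (vertical axis) against that of the dissociation and immediate early list (horizontal axis), one point per library, numbered by replicate. The knockout-labelled libraries lie at or above 7.92 on the horizontal axis and the wildtype-labelled libraries at or below 7.02.

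Among early response genes of T cell receptor signalling, Egr1 rose from 101 ± 29.0 to 292 ± 83.7 CPM and Egr2 from 25.7 ± 2.76 to 43.7 ± 1.56 CPM, 2 of 24 list members, or 14 adjusted over the list alone (median 0.78, camera adjusted p = 4.9e-07, and 0.218 with an estimated correlation). This list shares 2 members with the dissociation list, and with that list's mean as a covariate, a fit added after the data were seen, its call ended and its direction turned (median -0.45, adjusted p = 0.221). That covariate averages immediate early genes and separated the labels completely (at most 7.02 against at least 7.92). The lost call therefore cannot tell stress from T cell receptor signalling. Junb (964 ± 570 against 3647 ± 1101 CPM) and Tnfaip3 (302 ± 225 against 1521 ± 681 CPM) varied widely within each genotype and did not pass (adjusted p = 0.0577 and 0.0659). The TGF-beta response list had 3 of 20 members higher, the transcription factors Bhlhe40 (24.8 ± 12.0 to 186 ± 75.2 CPM) and Id2 (52.4 ± 14.8 to 136 ± 36.6 CPM) and the protease inhibitor Ctla2a (2.82 ± 0.604 to 9.96 ± 3.15 CPM). Adjusted over the list alone, 8 rose and 1 fell (camera adjusted p = 0.00109, and 0.313 with an estimated correlation), and the TGF-beta list also lost its call and turned with the stress covariate (median -0.26, adjusted p = 0.369). Of 23 apoptosis and p53 genes only Bbc3, which encodes PUMA, rose (15.1 ± 2.18 to 31.4 ± 5.80 CPM), with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00651, and 0.218 with an estimated correlation). No NF-kB target passed over all genes, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0276, and 0.375 with an estimated correlation). The NF-kB call was lost without wildtype replicate 1 (0.0923), wildtype replicate 3 (0.0762) and knockout replicate 3 (0.0677).

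A few interferon-stimulated genes and 1 ribosomal protein gene fell. In the type I interferon list, Ifit1 fell from 132 ± 13.1 to 58.9 ± 15.1 CPM (log2 fold change -1.17 ± 0.18, adjusted p = 0.0254) and Ifit3 fell as above, 2 of 38 members with none higher, or 5 adjusted over the list alone. The median was -0.22 (camera adjusted p = 0.00214, and 0.313 with an estimated correlation), and the list did not pass fry (adjusted p = 0.0734). In the interferon gamma list Gbp2, a guanylate-binding protein, fell from 183 ± 12.8 to 109 ± 12.1 CPM, and the other 31 tested members did not pass. Adjusted over the list alone, 2 were higher and 1 lower, and the list pointed up without passing (camera adjusted p = 0.538). Of 41 cytosolic ribosomal protein genes, Rps4x fell (576 ± 145 to 313 ± 10.5 CPM, adjusted p = 0.0440) and 40 did not pass, while 15 fell adjusted over the list alone (median -0.34, camera adjusted p = 5.2e-06, and adjusted p = 0.395 with an estimated correlation of 0.47), and that list did not pass fry either (0.123). The ribosomal median moved with the libraries used, from -0.22 without wildtype replicate 1 to -0.43 without wildtype replicate 3. Ribosomal protein genes have many processed pseudogenes that share their sequence, so single values are uncertain.

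**Figure D3:**
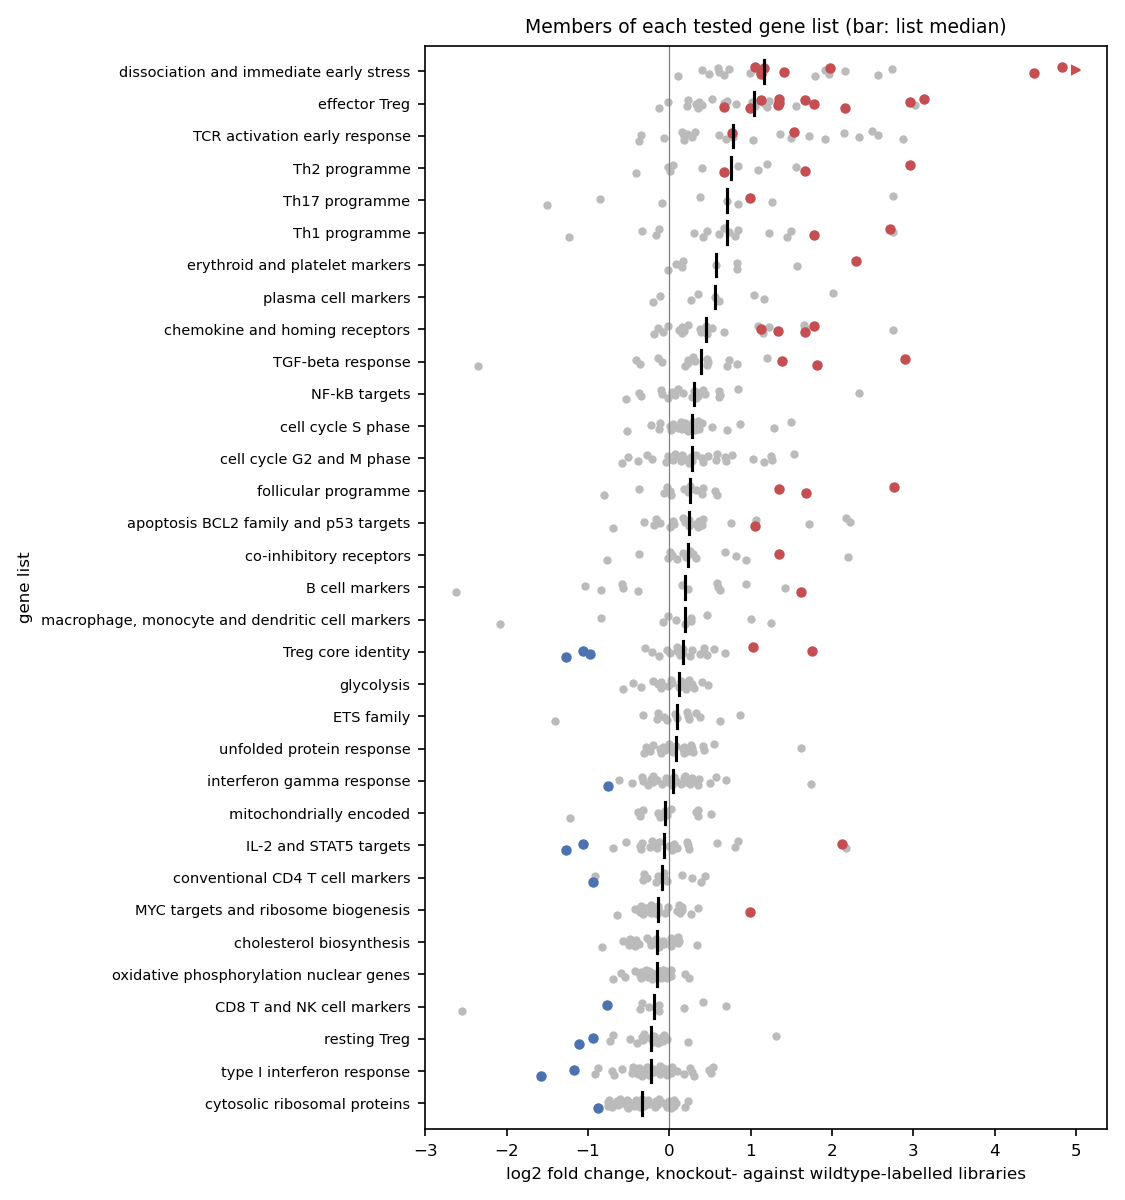
Log2 fold changes, knockout- against wildtype-labelled libraries, of the tested members of 33 gene lists, one row per list, with the list median as a black bar. Red points rose and blue points fell (adjusted p under 0.05), grey points did not pass, and the triangle marks Atf3, whose fitted value lies beyond the axis limit of 5. The dissociation and effector Treg lists have the highest medians (1.16 and 1.04) and the cytosolic ribosomal proteins the lowest (-0.34). Without wildtype replicate 1, which is not drawn, the resting Treg (-0.272), cholesterol (-0.228) and CD8 T and NK (-0.218) medians were below the ribosomal one (-0.216). Without knockout replicate 2, also not drawn, the resting Treg median (-0.335) was below the ribosomal one (-0.331).

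Metabolic and cell cycle lists shifted by little. The nuclear genes of oxidative phosphorylation had a median log2 fold change of -0.15, with none of 32 members called over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.00274, and 0.395 with an estimated correlation). Their median was -0.09 without wildtype replicate 1 and -0.24 without wildtype replicate 3. Cholesterol biosynthesis had none of 24 called (median -0.15, camera adjusted p = 0.0274, and 0.429 with an estimated correlation). Without 1 library at a time, the cholesterol call was lost for wildtype replicates 2 (0.139) and 3 (0.0608) and knockout replicates 1 (0.202) and 2 (0.120). The S phase and G2 and M phase lists, of 30 genes each, had medians of 0.28 and 0.28 with no member called over all genes or over the list alone (camera adjusted p = 0.00651 and 0.0276, and 0.218 and 0.313 with an estimated correlation). The G2 and M call was lost without wildtype replicates 2 (0.0580) and 3 (0.0762) and without knockout replicate 3 (0.339). In the fit without knockout replicate 3 the G2 and M median itself was only 0.04. Glycolysis (21 genes, none called, adjusted p = 0.553), the unfolded protein response (23 genes, none called over all genes and 1 higher over the list alone, 0.214) and MYC targets (29 genes, 0.151, with Odc1, the polyamine enzyme ornithine decarboxylase, rising from 53.1 ± 6.07 to 106 ± 24.4 CPM as its 1 call, also over the list alone) did not pass as lists. The 13 mitochondrially encoded genes had none called, a median of -0.06 and a mean of -0.08 with a camera direction of up (adjusted p = 0.701). That list passed in the opposite direction, down, without wildtype replicate 2 (0.0191), and passed as up without wildtype replicate 3 (0.0492).

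Markers of other cell types ranged from near 0 CPM to high levels, and few were called. The highest of 14 tested B cell markers was Ighm, the IgM heavy chain constant gene, with 1226 ± 238 CPM in wildtype-labelled and 1442 ± 34.1 CPM in knockout-labelled libraries (adjusted p = 0.485). Cd74, the invariant chain, rose from 33.1 ± 5.19 to 101 ± 13.6 CPM (log2 fold change 1.61 ± 0.16, adjusted p = 0.00627), while Cd79a had 2.36 ± 0.881 against 1.81 ± 0.264 CPM, Cd79b 23.0 ± 6.44 against 15.5 ± 1.60 CPM and Igkc 2.43 ± 0.315 against 6.50 ± 1.46 CPM (adjusted p = 0.0743). Adjusted over the list alone 2 B cell markers rose, and the list's camera adjusted p was 0.216. None of 9 plasma cell markers was called over all genes and 1 rose over the list alone (Prdm1, which the effector Treg list also holds, 18.0 ± 8.32 against 40.3 ± 4.48 CPM), with a camera adjusted p of 0.0239 that became 0.313 with an estimated correlation. The plasma cell call was lost without wildtype replicate 1 (0.0545) and without knockout replicate 3 (0.0786). None of 11 macrophage, monocyte and dendritic cell markers was called, the highest being the protease gene Ctsb with 473 ± 34.0 against 568 ± 45.6 CPM (list camera adjusted p = 0.315). Of 9 erythroid and platelet markers only Car2, a carbonic anhydrase, rose (2.38 ± 0.772 to 11.8 ± 1.53 CPM), and Hba-a1 had 0.514 ± 0.627 against 1.54 ± 0.196 CPM. The erythroid list's camera adjusted p was 0.0122, and 0.349 with an estimated correlation, and it was lost without wildtype replicate 2 (0.224) and without each of knockout replicates 1 (0.0584), 2 (0.0866) and 3 (0.0553). Among 10 CD8 T and NK cell markers the kinase gene Txk fell (183 ± 7.86 to 108 ± 8.36 CPM, 1 lower over the list alone, list adjusted p = 0.195), and among 15 conventional CD4 T cell markers Igfbp4 fell, with 2 lower over the list alone (list adjusted p = 0.166). Satb1, a chromatin organiser on that list, had 470 ± 7.52 against 375 ± 57.0 CPM. The single tested neutrophil marker was Mmp9, and the 2 tested sex-linked genes were not called, so those lists were not tested as sets.

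Over all lists, camera called 21 of 33, 16 upward and 5 downward, with a preset correlation of 0.01. With a correlation estimated from these libraries it called 0 of 33, the smallest adjusted p being 0.218. Lists whose estimated correlation lay below the preset, such as Th2 (-0.00839) and S phase (-0.0135), lost their calls too. The loss therefore cannot be read as the effect of correlated members alone. By direction fry called 12, all of them camera calls, and the remaining camera calls did not pass fry. These 12 were the effector Treg, resting Treg, dissociation, TCR, chemokine and homing, Th1, Th2, Th17, follicular, apoptosis, S phase and co-inhibitory lists. Splits of the libraries that mixed the genotypes also gave camera calls at the preset correlation, from 1 to 9 lists each, though part of any genotype difference remains in such splits. With the stress covariate, 5 of the 21 calls remained in the same direction (effector Treg, resting Treg, Th1, follicular, and chemokine and homing receptors). Besides the TCR and TGF-beta lists, the apoptosis (camera adjusted p = 0.683), erythroid (0.596) and oxidative phosphorylation (0.537) lists lost their calls and turned direction. The dissociation list did so too (0.683), but the covariate is its own mean, so that loss was fixed in advance and carries no information. Without scaling beyond total counts the median log2 fold change of all tested genes was -0.06, against -0.02 with TMM, and none of the list medians over 0.10 in size changed sign under TMM, RLE, upper-quartile or total-count scaling.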

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

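The fit with a stress covariate and the alternatives for library similarity were chosen after seeing the data. The count of 172 changed genes (118 at least 2-fold) stayed within 1.5 times under RLE, upper-quartile and total-count scaling and under limma-voom. It was 1046 (352) with DESeq2, 331 with quality weights in limma-voom, 385 (209) with no filter beyond 1 count in any library, 285 with at least 1 CPM in at least 3 libraries, and 495 at a threshold of 0.1. Leaving out 1 library gave 3 to 384 genes (3 to 226 at least 2-fold), with fewer libraries in the fit. With the mean of the dissociation list as a covariate, which overlaps with genotype, 0 genes passed (0 at least 2-fold, 717 at an unadjusted p under 0.05 in edgeR, no other tool run) and 6 lists did. Of the 172 called genes, 159 kept their direction in that fit and 13 turned. Their median log2 fold change in the main direction went from 1.37 to 1.08 and their median SE from 0.21 to 0.56. Fold changes thus shrank and errors widened, the errors by the larger factor. There 10 lists turned direction (TCR activation, TGF-beta, apoptosis, erythroid, ETS, Treg core, oxidative phosphorylation, CD8 T and NK, dissociation and mitochondrially encoded), the last passing as down (adjusted p = 0.0279). The dissociation list was adjusted for its own mean, so the loss of its rise was fixed in advance and carries no information. The count of 21 lists fell to 0 with an estimated correlation and 12 with fry, and was 16 to 19 without 1 library. For each of these differences the cause was not tested.

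All 73 called genes that the text and its naming rule single out kept their direction in each planned fit that gave a value. Their calls were lost for at most 5 genes under any scaling, tool or filter, for 25 with the replicate block, and for 71, 33 and 6 without wildtype replicates 1, 2 and 3, and 32, 53 and 63 without knockout replicates 1, 2 and 3. Etv3 ranged from 0.12 to 0.40 and passed in none of its planned fits (lowest adjusted p 0.192). Foxp3, at -0.02, was 0.0317 with quality weights, 0.16 without wildtype replicate 2 and 0.02 without knockout replicate 1, and ranged from -0.11 to 0.16 without 1 library. In planned fits direction turned for the mitochondrially encoded list without wildtype replicate 2 (adjusted p = 0.0191, highest without 1 library 0.970), glycolysis without wildtype replicate 3 (0.738, range 0.0539 to 0.967) and IL-2 and STAT5 targets without knockout replicate 1 (0.907, lowest 0.485). The lowest correlation within a genotype, 0.966, was 0.904 without the filter and 0.973 with the CPM filter. With the replicate block, 91 genes and 21 lists passed, 68 of the genes shared with the unblocked fit. Deviations of same-numbered libraries correlated at 0.09, -0.02 and -0.04, and not every library correlated best with its own number, so the numbers gave no sign of pairing. Depth limits what is said of genes at or under 0.0785 CPM.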

Other observations

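The tests of stress, cell mixture and position below were chosen only after the result was seen. The splits of the libraries were planned. The called genes in this paragraph were picked after their values were seen, and Etv3 counts were not lower in the knockout-labelled libraries. Atp6v0d2, a subunit of the vacuolar proton pump, had the smallest p of all genes and rose from 12.0 ± 2.70 to 96.6 ± 15.7 CPM (SD, n = 3 each; log2 fold change 3.01 ± 0.20, adjusted p = 0.00130). Nebl, an actin-binding protein gene, rose from 2.45 to 17.1 CPM, Pfn2 (profilin 2) from 8.38 to 28.4 CPM, Cybb, the NADPH oxidase catalytic subunit, from 38.0 to 106 CPM and Cd86, a co-stimulatory ligand, from 73.2 to 162 CPM. The prostaglandin E2 receptor genes Ptger2 and Ptger4 rose together, by log2 fold changes of 0.67 and 0.85, and so did the transcription factor genes Cebpb (15.0 to 79.6 CPM) and Nfil3. Among genes that fell were Rras2, a RAS-related GTPase (94.9 to 49.0 CPM), Itga6, an integrin chain (227 to 138 CPM), and Pecam1 (180 to 114 CPM). In 11 called genes, 1 genotype had 0 counts in each of its libraries.

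The real grouping called 172 genes, 118 of them at least 2-fold, and 21 lists. The highest of the other splits of the 6 libraries into 3 and 3 called 1 gene, 1 gene at least 2-fold and 9 lists, so only 1 of 10 splits reached each real value. With 10 splits the share cannot go under 0.1, too few to exclude chance. Each split that mixed the genotypes still called lists by camera with the preset correlation, from 1 to 9. Such splits hold unequal numbers of each genotype on each side. Part of any genotype difference thus stays between their groups and part widens the spread within them. Their counts are therefore not those of libraries without a genotype difference.

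The mean log2 CPM of the effector Treg list and of the dissociation list were both higher in each knockout-labelled library, and Il2ra, Gpr83 and Socs2 were lower. More conventional CD4 T cells in the sort would dilute alike those Treg identity transcripts that such cells lack, and the core list was not chosen by that criterion. The median log2 fold change of the 23 core identity members was 0.17 (95% order-statistic interval -0.02 to 0.43), so the list as a whole did not fall. The median of Il2ra, Gpr83 and Socs2 was -1.06. These genes were picked as the members of that list that fell, so their gap from its median was nearly fixed in advance and decides nothing. Members of the list moved both ways (2 rose and 3 fell over all genes), so its median is an imperfect gauge of dilution. The sort marker Foxp3 had 360 ± 72.2 against 354 ± 21.5 CPM (log2 fold change -0.02 ± 0.15, SE). That neither the list median nor Foxp3 fell by as much argues against dilution alone as the source of a fall of that size. A smaller dilution is not excluded. Handling stress is a candidate explanation for the effector shift. With the dissociation list as a covariate, the genotype difference in the mean log2 CPM of the effector list was 1.07 (95% interval -0.98 to 3.12) against 1.11 (0.58 to 1.64) without it, and the list still passed camera (adjusted p = 4.0e-05 with the preset correlation). The point estimate hardly moved, but stress and genotype overlap so much that the interval holds 0 and both stay open, as does a change in the share of effector cells among Tregs.

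The rise of heat shock and immediate early genes is the pattern that a different handling time or temperature could give. The lowest knockout-labelled library exceeded the highest wildtype-labelled one by 0.90 in mean log2 CPM of the list, which fits handling and genotype equally, and the labels name no sort day, so they cannot be told apart. Dying cells might also raise these genes. The mitochondrially encoded share of counts was 3.75% ± 0.183 in knockout-labelled and 3.33% ± 1.06 in wildtype-labelled libraries (SD, n = 3 each), a difference of 0.422 percentage points (95% interval -1.30 to 2.14) that leaves this open. An effect of Etv3 itself also stays open and was not tested.

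Fcrl1, an Fc receptor-like gene of B cells at 87376387 to 87402934 on chromosome 3 (mm10, protein-coding), ends 122 kb before Etv3 and rose from 11.3 ± 2.94 to 38.8 ± 8.57 CPM (log2 fold change 1.78 ± 0.24, adjusted p = 0.0155). Fam160a1 (85660061 to 85817291) and Glt28d2 (85869849 to 85887516), on the same chromosome, rose by log2 fold changes of 2.07 and 1.76. Gm37240, which spans both Fam160a1 and Glt28d2 on the same strand (0.146 against 1.76 CPM, adjusted p = 0.0526), and Insrr (87796951 to 87816101, 0 against 0.512 CPM, adjusted p = 0.0583) were higher without passing. Because Gm37240 overlaps both, the calls of Fam160a1 and Glt28d2 may not be independent of each other. Insrr lies within Pear1 (87747890 to 87824306, log2 fold change 0.63 without passing, adjusted p = 0.161). It had only 22, 14 and 25 counts in knockout-labelled libraries 1, 2 and 3, so it may not be a separate neighbour that rose. One hypothesis is that DNA around Etv3 differs between the genotypes beyond the targeted exons. Of 258 tested genes within 10 Mb of Etv3, 3 were called (1.16%), against 163 of 15405 elsewhere (1.06%), with an odds ratio of 1.10 (95% interval 0.223 to 3.31; Fisher's exact test, 2-sided p = 0.755), so calls showed no excess, but one of up to 3.31-fold is not excluded. At an unadjusted p under 0.05 in edgeR there was an excess: 56 of the 258 (21.7%, 26 higher and 30 lower) against 2366 elsewhere (15.4%), an odds ratio of 1.53 (95% interval 1.11 to 2.07; Fisher's exact test, 2-sided p = 0.00698), and 2.88% of windows of as many genes held as many. Neighbouring genes are not independent and this test was added last, so the explanation stays open, and a narrower cluster was not tested. B cells in the sort, which the bead depletion and the CD4 gate would remove, are a poor candidate source of Fcrl1. Cd79a, abundant in B cells, was at 1.81 ± 0.264 CPM in the knockout-labelled libraries, far below Fcrl1 itself. The 12 B cell markers under 30 CPM in wildtype-labelled libraries, a limit set after the values were seen, had a median log2 fold change of -0.11 (95% order-statistic interval -0.83 to 0.62). That limit leaves out Ighm and Cd74 (33.1 CPM), the latter of which rose by a log2 fold change of 1.61, and Igkc, within it, had 1.42 without passing.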
